A study of Mus musculus with 454 samples.

How the data were processed

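The series holds 454 mouse brain libraries with a single table of values for all of them. Per the labels' protocols, total RNA was taken up in QIAzol and purified on RNeasy columns with DNase treatment. Polyadenylated RNA from 300 ng went into stranded TruSeq mRNA libraries, which were pooled by 21 and read as 50-base single ends on a HiSeq2500. The labels do not say which library was in which pool. The values are counts of reads per gene, as deposited by the authors. Per the submitters' processing notes, STAR, featureCounts and limma were used, with the genome build GRCm38/mm10. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Counts of genes that overlap on opposite strands are therefore uncertain, and so are counts of near-identical genes such as clustered protocadherins.

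The table has 43346 genes, of which 42462 carry a symbol. The 884 without a symbol hold 0.11% of all counts and stayed in library sizes and tests under their identifiers, and none of them is named. The table names genes by Ensembl identifier only. Symbols were matched by identifier to a table of gene names, and coordinates come from the GENCODE M21 annotation of GRCm38, so neither is the authors' own. Each library was placed in a group by the labels for region, sex, housing, cocaine dose and schedule, which gave 64 groups in 4 regions. Library totals ran from 11.21 to 52.34 M (mega-counts), with a median of 21.71 M, so that 1 CPM (1 count per mega-count) stands for about 22 reads in a typical library. Several genes under that level are given with their mean. No libraries were merged: the most alike pair within a group still differed by a chi-square per degree of freedom of 2.795, well above sampling noise. Sex labels were checked with Xist and Y-linked genes, and region labels with marker lists. The opposite-sex percentage of a female library is its CPM of Ddx3y, Uty, Kdm5d and Eif2s3y over the median of the males of the region, and that of a male library is its Xist CPM over the median of the females. A library counted as contradicting its label when its opposite-sex transcripts reached 5% of the median of the other sex. It counted as standing apart when its robust z was over 5 on any of the first 4 principal components of 3000 variable genes, or over 8 on a marker list of a tissue other than its own region and the pituitary. This gave 6 libraries in AMY, 11 in Nac, 7 in PFC and 8 in VTA.

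Each region was fitted apart in R 4.3.3 with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest), with the 16 groups as cell means, filterByExpr on low counts and TMM normalization factors. Every adjusted p in the text is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested in that region and comparison, unless camera or another tool is named, and the threshold was 0.05. A few counts of genes are rounded in the text: the chronic saline groups alone gave 1060 genes for housing in females and 1206 for sex in isolation in Nac, and at an unadjusted p under 0.05 there were 1141 genes with acute cocaine in VTA and 524 in PFC for its differences between combinations. The tests covered 17391 genes in AMY, 17266 in Nac, 17003 in PFC and 17144 in VTA. Standard errors are on the log2 scale. CPM values are given as mean ± SD over libraries. Most were scaled over the genes that pass the filter in the libraries of a fit. Values of Crym in single libraries, of Ttr in VTA with acute treatment and in plots were scaled over all genes of a region, and values by number series over all 454 libraries, so that the same library can differ slightly between them. All tests were two-sided. The comparisons were sex in group-housed and in isolated saline mice, the change of the sex difference with housing, housing in each sex under saline, acute and chronic cocaine against saline, and an F test of whether each cocaine effect differed between the 4 combinations of sex and housing. This made 9 comparisons in each of 4 regions. Gene lists (34) were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a region and comparison. The calls that hold with an estimated correlation are given where they occur.

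Groups, comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took genes past the threshold with a mean of at least 1 CPM and a symbol that is not that of an unnamed gene model: in AMY the 10 with the largest rise and the 10 with the largest fall, in the other regions 5 and 5. Sex chromosome genes of a fixed list were given apart. In the F tests and the change of the sex difference with housing, the 10 genes with the lowest p past the threshold were taken in AMY and 5 elsewhere, and where no gene passed, the 3 with the lowest p were taken. Up to 4 members of a list could serve as examples, and Crym was added because the study is known to have taken it up. Chosen after values were seen were the comparisons of sex and of housing over all groups, the comparison of chronic with acute cocaine within number series 1000, the protocadherin counts and the genes said in the text to be named after their values were seen. Some genes that the rule takes are not reported here.

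The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, the number series of the sample titles as a covariate, 3 surrogate variables (sva 3.50.0), and fits without libraries that contradict their labels. Each of the 5 libraries of the smallest AMY group was left out in turn. Added after the data were examined were fits without libraries that stand apart, the acute or the chronic saline groups alone, single number series, and a striatal marker covariate in PFC. Also added was a test on separate libraries of PFC: genes were chosen with edgeR between chronic cocaine of series 1000 (n = 20) and chronic saline of series 500 (n = 10). Their mean log2 CPM, each gene signed by its direction, was then compared between cocaine and saline within series 1200 by exact permutation within sex and housing. The number series groups title numbers by their leading digits (500, 1000, 1100 or 1200). The labels do not say that it marks a batch, and it was treated as a technical grouping because every series holds both sexes and both housing conditions. Tables were prepared in R with the package data.table (version 1.17.8) and in Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

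The tests were tested on simulated data: counts for the real genes of each of the 4 regions, with 200 genes changed by known folds. The recovered shares are given for AMY. For housing in males over 17391 genes, edgeR recovered 58.2% of the genes changed 1.2-fold, 89.6% of those changed 1.5-fold and 100.0% of those changed 2-fold. There were 6 false calls among 171. For acute cocaine the shares were 76.1%, 98.5% and 97.0%, and for a cocaine effect that differs between sex and housing combinations 9.0%, 58.2% and 65.2%. False calls were 12 of 193 for acute cocaine in AMY. Over all regions they ran from 4 of 157 (sex in group housing, Nac) to 18 of 185 (acute cocaine, Nac). They were 17 of 176 for housing in males of Nac and 16 of 202 for acute cocaine in VTA. Some comparisons thus held a larger share of false calls than the adjusted p threshold aims at. Camera called 2 of 2 changed lists and 0 of 30 unchanged ones. The simulated genes were drawn independently and the unchanged lists were random genes. This result therefore does not show how camera at the preset correlation treats lists of correlated genes.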

Results

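The series asks how social isolation during adolescence bears on gene expression and on sex differences in brain regions of reward, with the medial amygdala named in its title. RNA-seq was run on 454 mouse brain libraries from 4 regions, which the labels call AMY (115 libraries), Nac (112), PFC (112) and VTA (115), the usual short names of amygdala, nucleus accumbens, prefrontal cortex and ventral tegmental area. Females and males had been housed in groups or socially isolated. They received saline or cocaine at 7.5 mg/kg on an acute or a chronic schedule, which gave 16 groups per region and 64 in all. The groups held 5 to 8 libraries. The smallest was the isolated males with acute cocaine in AMY (n = 5). The labels do not say that libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. The sample titles carry 129 numbers, 86 of which recur in all 4 regions, always with the same sex, housing and treatment.

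Total counts ran from 11.21 to 52.34 M (mega-counts) per library with a median of 21.71 M. They were 13.67 to 34.52 M in AMY, 11.21 to 32.08 M in Nac, 13.51 to 52.34 M in PFC and 13.99 to 51.34 M in VTA. Marker genes followed the region labels. The striatal neuron list averaged 7.55 on the log2 CPM scale, where CPM is the count per mega-count of the library, in Nac, against 4.65 in AMY, 4.05 in PFC and 3.96 in VTA. The dopamine neuron list averaged 6.97 in VTA and at most 2.06 in another region, and the cortical glutamatergic list was highest in PFC, at 6.61. The medial amygdala and hypothalamic list averaged 4.64 in AMY, 3.66 in Nac, 3.08 in VTA and 2.55 in PFC. Xist, the RNA of the silenced X chromosome, had a median between 410.8 CPM (VTA) and 1256 CPM (Nac) in females and reached at most 51.9 CPM in a male library. In 3 female libraries, 1 in AMY and 2 in Nac, the Y-linked transcripts reached 5.87%, 8.47% and 35.0% of the median of the males of the region.

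Sex differences under saline were the question closest to the series title, and they were measured in group-housed and in isolated mice apart. In AMY of group-housed mice, Sytl4 (a synaptotagmin-like protein of vesicle trafficking; chromosome X, 133936385 to 133981812, GRCm38/mm10, minus strand) was lower in females, at 4.39 ± 1.71 CPM (SD, n = 13) against 10.7 ± 3.54 CPM in males (n = 15). Its log2 change, females minus males, was -1.28 (SE 0.21, edgeR adjusted p = 2.23e-05), and 0 of 13 female libraries lay above the male median. Xist was higher in females by 8.48 on the log2 scale, and the Y-linked Ddx3y (-9.05), Uty (-8.71), Kdm5d (-8.62) and Eif2s3y (-8.89) were found in males. The X-linked genes Eif2s3x (0.61), Kdm6a (0.46), Ddx3x (0.44) and Kdm5c (0.43), which are known to escape X inactivation, were higher in females. In all, 8 genes were higher and 7 lower in group-housed females, and all 15 lay on X or Y.

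In isolated mice, 7 genes were higher and 6 lower in AMY of females, 12 of them on X or Y. The other gene was Tmem174 (1.29, SE 0.24, adjusted p = 9.21e-04, mean 0.423 CPM), named here after its value was seen. Sytl4 measured 4.58 ± 1.78 CPM in isolated females (n = 14) and 8.0 ± 3.77 CPM in isolated males (n = 15), and its difference of -0.80 (SE 0.21) had an adjusted p of 0.172. Rbbp8, a DNA repair factor (-0.38, SE 0.09, adjusted p = 0.0508), and the collagen gene Col25a1 (-0.23, SE 0.06, adjusted p = 0.124) had lower p-values. Between the housing conditions, 6 of the genes higher in females and 6 of those lower were shared (0.0032 and 0.0024 for independent lists). All the shared genes lie on X or Y and would separate the sexes in any housing. The sharing therefore says nothing about housing. The change of the sex difference with housing, tested directly, gave 0 genes with edgeR, 643 at an unadjusted p under 0.05 where chance gives 870, and 0 with DESeq2 and with limma voom. The edgeR call of Sytl4 in group-housed mice was lost in the acute saline groups alone (-1.08, adjusted p = 0.585) and held in the chronic ones (-1.49, adjusted p = 0.0016).

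**Figure D1:**
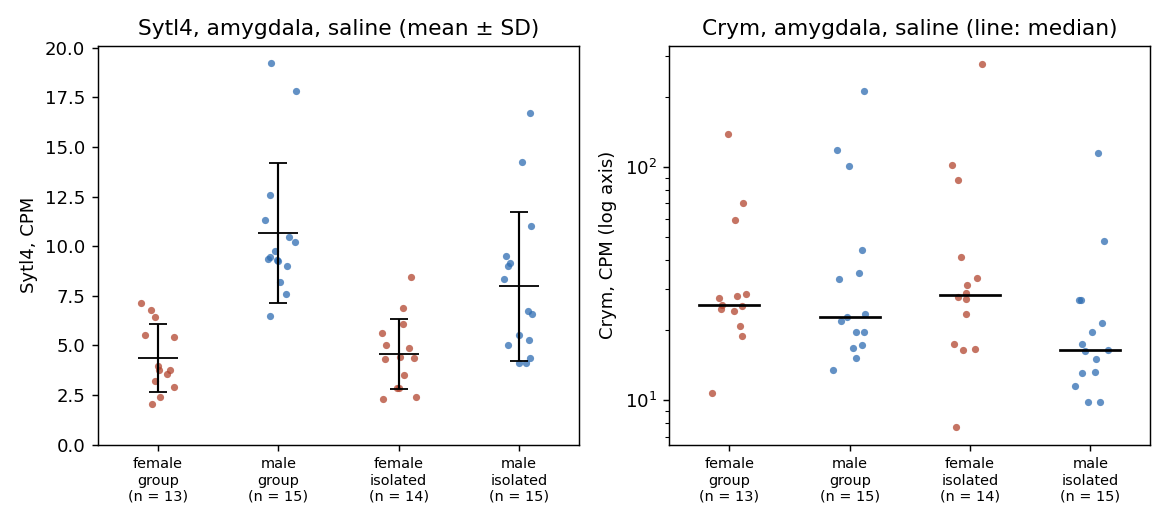
CPM of Sytl4 (left, linear axis from 0, lines show mean ± SD) and Crym (right, log axis, lines show medians) in the saline libraries of AMY, 1 point per library, by sex and housing. Sytl4 lies between 2.03 and 7.16 CPM in group-housed females (n = 13) and between 6.48 and 19.2 CPM in group-housed males (n = 15). Crym spreads from 7.72 to 276.8 CPM among isolated females (n = 14).

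Crym (mu-crystallin, a protein that binds thyroid hormone; chromosome 7, 120186380 to 120202111) is a gene the study of this series is known to have taken up, and it was set apart for that reason. It did not pass the test in any saline comparison of AMY. In isolated mice it measured 53.0 ± 70.9 CPM in females (n = 14) and 25.6 ± 26.9 CPM in males (n = 15), a difference of 1.01 (SE 0.40, edgeR adjusted p = 0.746), with 12 of 14 female libraries above the male median. In group-housed mice the means were 38.9 ± 34.9 CPM and 47.8 ± 55.8 CPM, with a difference of -0.23 (SE 0.40, adjusted p = 0.989). That difference was 0.15 with limma voom and 0.05 without the libraries that stand apart. The change of the sex difference with housing was 1.24 (SE 0.57, unadjusted p = 0.0313, adjusted p = 1.0) and 1.29 with the number series in the model. Isolation moved Crym by -0.82 (SE 0.39, adjusted p = 0.891) in males and by 0.41 (SE 0.41, adjusted p = 1.0) in females.

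Over all 8 pairs of groups that differ only in sex, a comparison added after the data were examined, more genes separated the sexes. In AMY, 149 genes were higher and 224 lower in females (n = 59) than in males (n = 56), 339 of the 373 on autosomes. Greb1, a gene known to be induced by sex steroids (chromosome 12, 16670615 to 16800886), measured 2.51 ± 1.96 CPM in females and 7.14 ± 8.83 CPM in males (log2 change -1.49, SE 0.20, edgeR adjusted p = 5.13e-08, lower in females in 8 of 8 pairs of groups). Cyp19a1, the aromatase that makes oestrogen from androgen (chromosome 9, 54165937 to 54268110), differed by -0.85 (SE 0.23, adjusted p = 0.0321, 7 of 8 pairs). This was -0.78 (adjusted p = 0.0659) without the libraries that stand apart. Sytl4 differed by -0.99 (SE 0.10, adjusted p = 5.80e-13, 8 of 8 pairs), and 58 of 59 female libraries lay below the male median. The neuropeptide galanin (Gal; chromosome 19, 3409915 to 3414544) differed by -0.66 (SE 0.16, adjusted p = 0.0077, 8 of 8). Rasd1, a small GTPase induced by glucocorticoids, differed by -0.48 (SE 0.07, adjusted p = 1.50e-06, 7 of 8). Higher in females were the activin subunit gene Inhba (0.40, SE 0.10, adjusted p = 0.0175), the parathyroid hormone receptor family member Pth2r (0.34, SE 0.08, adjusted p = 0.0055), the neuropeptide cortistatin (Cort, 0.31, SE 0.09, adjusted p = 0.0479) and the thrombin receptor family member F2rl2 (0.43, SE 0.09, adjusted p = 0.0022), each in 8 of 8 pairs.

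Of the 15 measured genes of sex steroid signalling, 0 were higher and 3 lower in females in AMY, and 4 were lower adjusted over the list alone (camera adjusted p = 0.0056; adjusted p = 0.374 with an estimated correlation). Of 22 astrocyte genes, 5 were lower, among them the gap junction gene Gja1 (-0.17, SE 0.03, adjusted p = 3.70e-04), and 9 were lower adjusted over the list alone (camera adjusted p = 1.97e-08; adjusted p = 0.374 with an estimated correlation). Choroid plexus genes, markers of the tissue that lines part of the brain ventricles, were lower with them: 4 of 25 passed, 19 adjusted over the list alone (camera adjusted p = 1.97e-08; adjusted p = 0.520 with an estimated correlation), with Ttr at 88.3 ± 492 CPM in females and 279 ± 905 CPM in males. All 6 AMY libraries that stand apart do so on the choroid plexus list, and 5 of them are from males. Without them Ttr differed by -0.63 (SE 0.21, adjusted p = 0.111) against -1.81 (adjusted p = 0.0036) with them. Within number series 500, 1000, 1100 and 1200 of the sample titles, Sytl4 differed by -1.18, -1.12, -0.73 and -1.10, Greb1 by -1.19, -1.95, -0.31 and -1.44, Gal by -1.32, -0.53, -0.47 and -1.34, and Cyp19a1 by -0.94, -1.26, 0.02 and -1.14. The edgeR count rose to 922 with 3 surrogate variables, of which 350 were among the 373, and to 576 with limma voom.

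In the other regions the pooled comparison gave 31 higher and 16 lower genes in Nac, 76 and 123 in PFC and 32 and 28 in VTA. Some of the clustered protocadherins, neuronal cell surface proteins encoded side by side, were higher in females in each region: 16 of 55 measured members in AMY, 7 of 55 in Nac, 10 of 54 in PFC and 10 of 55 in VTA, with 1 lower in AMY and 0 lower elsewhere. This family was picked out after its values were seen, and it was not tested for enrichment. Pcdhb6 (chromosome 18, 37333921 to 37337674) was higher by 0.22 (SE 0.04, edgeR adjusted p = 5.86e-04) in AMY, 0.27 (SE 0.05, adjusted p = 0.0011) in Nac and 0.28 (SE 0.04, adjusted p = 4.61e-07) in VTA, in 6, 8 and 8 of 8 pairs of groups. Its values in series 500, 1000, 1100 and 1200 were 0.21, 0.29, 0.18 and 0.15 in AMY, 0.23, 0.24, 0.24 and 0.37 in Nac and 0.27, 0.25, 0.33 and 0.29 in VTA. Other members went the opposite way in series 500. In Nac these were Pcdhb2 (-1.48, adjusted p = 0.0126), Pcdhb14 (-0.25), Pcdhb4 (-0.13) and Pcdhb8 (-0.09), in a fit of 3 females and 7 males that called 7835 genes. Of these 3 females, replicate 6 of the isolated group with chronic saline stands apart. In VTA it was Pcdha7 (-0.15) and in PFC Pcdhb9 (-0.08). These genes resemble each other in sequence, and reads of 50 bases may be split between them. In Nac, Col26a1, a collagen gene (chromosome 5, 136741759 to 136883209), was higher in females both over all groups (0.33, SE 0.06, adjusted p = 4.41e-05, 8 of 8 pairs) and in the group-housed saline mice (0.49, SE 0.11, adjusted p = 0.0291, 12 of 12 female libraries above the male median). The second of these was 0.53 (adjusted p = 0.0739) without the libraries that stand apart. In PFC, Hsd11b1, which regenerates active glucocorticoid, was lower in females (-0.26, SE 0.05, adjusted p = 7.85e-05, 7 of 8), as were the smooth muscle genes Acta2 (-0.45, SE 0.11, adjusted p = 0.0223) and Myh11 (-0.43, SE 0.10, adjusted p = 0.0108). In series 500, 1000, 1100 and 1200, Acta2 differed by 0.10, -0.30, -0.25 and -1.24. Over the same series Myh11 differed by -0.13, -0.30, -0.21 and -1.01 and Hsd11b1 by -0.21, -0.31, 0.01 and -0.54. Of 23 endothelial genes in PFC, 4 were lower in females and 16 adjusted over the list alone (camera adjusted p = 3.04e-12; adjusted p = 0.449 with an estimated correlation). The lists of AMY and PFC shared 16 genes higher in females (0.518 for independent lists) and 19 lower (1.477), though libraries with the same number are in both regions.

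In the saline groups alone, sex changed 17 genes in Nac, 11 in PFC and 11 in VTA of group-housed mice, and 14, 13 and 12 in isolated mice. Of these, 13, 11 and 11 in group-housed and 12, 11 and 11 in isolated mice lay on X or Y. Nlrp3, an inflammasome sensor, was higher in group-housed females in Nac (0.53, SE 0.13, edgeR adjusted p = 0.050, 11 of 12 libraries). Siglec1, a macrophage receptor, was higher in isolated females in PFC (1.28, SE 0.29, adjusted p = 0.0446, mean 0.358 CPM), and Pcdha8 was higher in isolated females in VTA (1.01, SE 0.21, adjusted p = 0.0108, mean 0.367 CPM), both named after their values were seen. The change of the sex difference with housing gave 0 genes in Nac, PFC and VTA with edgeR, DESeq2 and limma voom, with 2590, 591 and 280 genes at an unadjusted p under 0.05. In Nac isolated females, 53 of 83 ribosomal protein genes and 65 of 91 nuclear genes of oxidative phosphorylation were higher than in males adjusted over the list alone, and 0 of either passed over all genes (camera adjusted p = 8.01e-10 and 4.03e-13; adjusted p = 0.760 for both with an estimated correlation). The ribosomal list averaged 6.94 ± 0.617 log2 CPM in these females and 6.77 ± 0.108 in the males. Replicate 6 of the isolated females with chronic saline stands apart from the other Nac libraries.

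Few genes passed the threshold between isolated and group-housed mice, which does not show that isolation left the other genes unchanged. In AMY of males, 0 genes were higher and 1 was lower in isolated mice, Gm26644 (-3.49, SE 0.67, edgeR adjusted p = 0.0084, mean 0.112 CPM), named after its value was seen. It was lost with DESeq2 and limma voom, which called 0, and without the libraries that stand apart. Among the genes with the next lowest p were Magi3, a synaptic scaffold (102.4 ± 9.76 CPM in isolated against 88.7 ± 7.80 CPM in group-housed males, n = 15 and 15, log2 difference 0.21, SE 0.05) and Sphkap (0.22, SE 0.06). Their adjusted p was 0.891 each, with 14 of 15 isolated libraries above the group-housed median for both. In AMY of females, edgeR called 0 genes, with 442 at an unadjusted p under 0.05 and 0 with DESeq2 and limma voom. Srd5a1, the 5-alpha reductase of steroid metabolism, measured 9.08 ± 0.76 CPM in isolated and 8.03 ± 0.73 CPM in group-housed females (0.17, SE 0.05, adjusted p = 1.0).

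Housing gave 0 genes in males and females of Nac (447 and 2334 at an unadjusted p under 0.05), PFC (690 and 255) and VTA (585 and 485) with edgeR, and 0 with DESeq2 and limma voom. In Nac of females, 71 of 91 nuclear oxidative phosphorylation genes and 66 of 83 ribosomal protein genes were higher in isolation adjusted over the list alone (camera adjusted p = 7.43e-21 and 6.22e-18; adjusted p = 0.942 for both with an estimated correlation). For Rpl37a, a ribosomal protein gene, the mean was 198 ± 337 CPM in isolated females (n = 12) and 97.2 ± 10.2 CPM in group-housed ones (n = 12), with 8 of 12 above the group-housed median and an adjusted p of 0.173. In the chronic saline groups alone, about 1.1e+03 genes passed in females of Nac and 1.2e+03 between isolated females and males, and replicate 6 of the isolated female chronic saline group stands apart from the other Nac libraries. Without the libraries that stand apart, housing gave 0 genes in females of Nac over both schedules, as it did with them, so this does not show their effect. The chronic saline groups alone were not fitted without them. Pooled over all 8 pairs of groups that differ in housing, also added after the data were examined, edgeR again called 0 genes in each region, with 724, 413, 413 and 560 at an unadjusted p under 0.05 in AMY, Nac, PFC and VTA, and 0 with DESeq2 and limma voom. Of 28 myelin genes in Nac, 0 passed over all genes and 21 were higher in isolated mice adjusted over the list alone (median log2 change 0.12, camera adjusted p = 1.96e-35; adjusted p = 0.0427 with an estimated correlation).

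Acute cocaine, compared with acute saline over both sexes and housing conditions, changed genes in PFC. Sik1, a salt-inducible kinase gene that responds to neuronal activity (chromosome 17, 31844250 to 31855804), rose from 14.7 ± 3.35 CPM (n = 28) to 19.9 ± 3.78 CPM (n = 30), by 0.44 on the log2 scale (SE 0.09, edgeR adjusted p = 0.0175), with 28 of 30 cocaine libraries above the saline median. Zfp189, a zinc finger gene (chromosome 4, 49521176 to 49531517), rose from 11.4 ± 2.17 to 14.2 ± 2.08 CPM (0.32, SE 0.07, adjusted p = 0.0175, 28 of 30). Maff (0.48, SE 0.09, adjusted p = 0.0078), Gem (0.49, SE 0.11, adjusted p = 0.0219; chromosome 4, 11704457 to 11714752) and the stress-responsive Ddit4 (0.26, SE 0.06, adjusted p = 0.0175, 29 of 30) rose as well. Flrt3, a neuronal adhesion gene (chromosome 2, 140650914 to 140671469), fell from 28.7 ± 2.41 to 24.8 ± 2.61 CPM (-0.21, SE 0.04, adjusted p = 0.0039), with 1 of 30 libraries above the saline median. Gpr22 (-0.22, SE 0.05, adjusted p = 0.0219), Ankrd49 (-0.20, SE 0.04, adjusted p = 0.0111) and the transcription factor gene Klf6 (-0.17, SE 0.03, adjusted p = 0.0155) fell with it. In all, 7 genes rose and 4 fell.

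**Figure D2:**
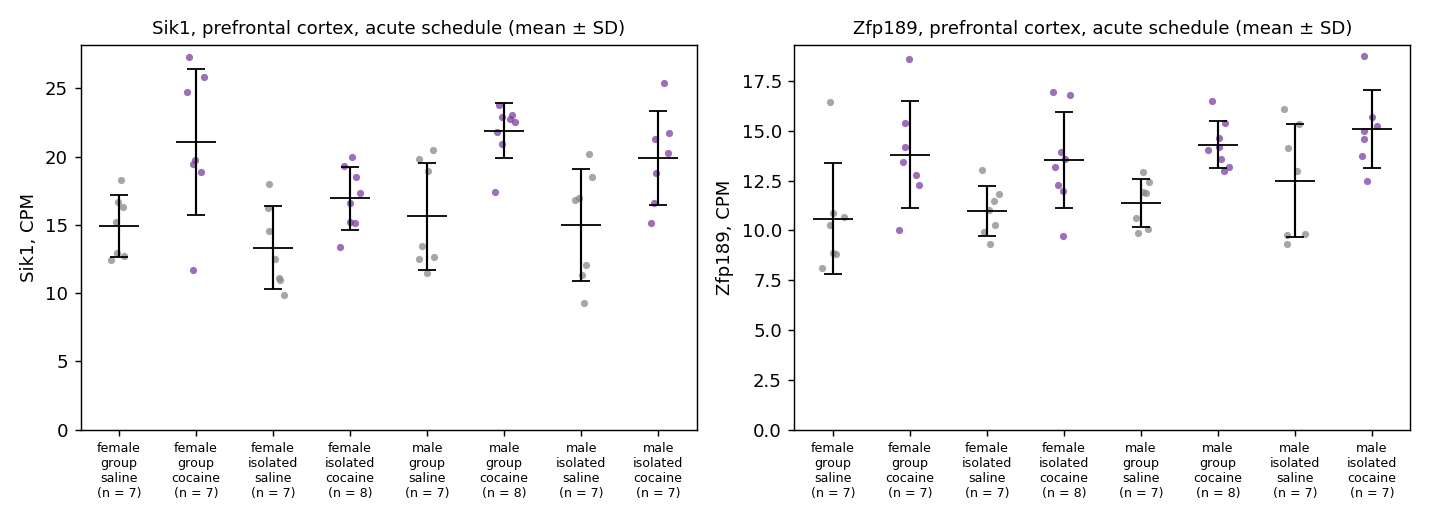
CPM of Sik1 (left) and Zfp189 (right) in PFC on the acute schedule, 1 point per library, by sex, housing and treatment, with linear axes from 0 and lines for mean ± SD in each group. Over all groups Sik1 averages 14.7 CPM with saline (n = 28) and 19.9 CPM with cocaine (n = 30), and Zfp189 averages 11.4 and 14.2 CPM.

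Of 45 immediate early genes measured in PFC, which neurons switch on within minutes of activity, 2 rose and 1 fell with acute cocaine, and 17 rose and 1 fell adjusted over the list alone (median log2 change 0.14, camera adjusted p = 1.88e-08; adjusted p = 0.611 with an estimated correlation). Of 28 glucocorticoid-induced genes, Ddit4 rose, and 4 rose adjusted over the list alone (camera adjusted p = 5.08e-07; adjusted p = 0.366 with an estimated correlation). Among these, Per1 differed by 0.21 (SE 0.06, adjusted p = 0.215) and Fkbp5 by 0.16 (SE 0.05, adjusted p = 0.321) over all genes. Markers of other cells moved in the same comparison: the median log2 difference was 0.15 for 28 myelin genes, with 0 past the threshold (camera adjusted p = 5.39e-04; adjusted p = 0.846 with an estimated correlation). Within number series 1000 and 1100, Sik1 differed by 0.40 (adjusted p = 3.94e-04) and 0.53 (adjusted p = 0.0332), Zfp189 by 0.29 (adjusted p = 0.566) and 0.39 (adjusted p = 0.0025), Flrt3 by -0.22 (adjusted p = 0.0278) and -0.21 (adjusted p = 0.370) and Ddit4 by 0.25 (adjusted p = 0.101) and 0.30 (adjusted p = 0.157). Sik1 changed by 0.50 and 0.49 in group-housed females and males and by 0.35 and 0.40 in isolated females and males. Gem changed by 0.74 and 1.25 in group-housed and by -0.18 and 0.14 in isolated females and males, and the test of a difference between these 4 gave an adjusted p of 0.360. That test gave 0 genes in PFC with edgeR, with about 5.2e+02 at an unadjusted p under 0.05, 0 with DESeq2 and 16 with limma voom. With limma voom, 143 genes changed with acute cocaine in PFC, and 32 did with edgeR without the libraries that stand apart.

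In AMY, Nac and VTA, edgeR called 0 genes with acute cocaine, with 550, 899 and about 1.1e+03 at an unadjusted p under 0.05. DESeq2 called 0, 2 and 13, and limma voom 0, 0 and 404. With the number series as a covariate edgeR called 0, 0 and 3, those of VTA being Slc17a7 (1.55, SE 0.32, adjusted p = 0.0499), Rspo4 (-0.87) and Clec18a (0.92), the latter pair named after their values were seen. Series 1000 alone gave 496 genes in VTA. Ddit4 was among the lowest p in AMY, at 41.4 ± 5.78 CPM with cocaine (n = 28) and 36.9 ± 5.90 CPM with saline (n = 27), a difference of 0.18 (SE 0.05, adjusted p = 0.999), with 23 of 28 above the saline median. Glucocorticoid-induced genes leaned the same way in these regions without a gene past the threshold: adjusted over the list alone, 1 of 28 was higher in AMY, 2 in Nac and 6 in VTA (camera adjusted p = 2.06e-07, 4.43e-07 and 9.57e-11; adjusted p = 0.440, 0.257 and 0.129 with an estimated correlation). In VTA, Pdk4 differed by 0.24 (SE 0.06, adjusted p = 0.144) and Nfkbia by 0.20 (SE 0.06, adjusted p = 0.236). Pcsk5, a proprotein convertase, had the lowest p in VTA (-0.43, SE 0.09, adjusted p = 0.0790), followed by the glutamate transporter genes Slc17a8 (-1.59, SE 0.35, adjusted p = 0.0970) and Slc17a7 (1.5, SE 0.34, adjusted p = 0.101). Within series 1000 and 1100, Pcsk5 differed by -0.19 and -0.54, Slc17a8 by 0.35 and -2.17 and Slc17a7 by 0.56 and 1.59.

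The effect of acute cocaine differed between the 4 combinations of sex and housing for 56 genes in VTA, led by transcripts of the choroid plexus: Ttr (edgeR adjusted p = 4.97e-05), Kl, F5 and Folr1 (4.85e-04 each) and Clic6 (8.40e-04). Of the 56, 19 belong to the choroid plexus list. Ttr measured 1474 ± 3622 CPM in isolated females with cocaine (n = 8), 688 ± 1781 CPM in isolated males with cocaine (n = 7) and 284 ± 759 CPM in group-housed males with saline (n = 8). In the remaining acute groups its mean lay between 6.00 and 13.4 CPM. A single library in the first of these groups reached 10374 CPM. Without the libraries that stand apart, 4 genes differed, and 1 did with 3 surrogate variables, 93 with DESeq2 and 2391 with limma voom. The same test gave 0 genes in AMY and Nac, with 905 and 760 at an unadjusted p under 0.05, 4 and 1 with DESeq2 and 0 and 9 with limma voom.

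Chronic cocaine was compared with chronic saline, and here the number series of the titles limit what can be said: series 500 held chronic saline alone (14 numbers), series 1000 held chronic cocaine but no chronic saline (24 numbers), and only series 1200 held both (8 and 19 numbers). In AMY the transcripts of the pituitary hormones prolactin (Prl; chromosome 13, 27057570 to 27065205) and growth hormone (Gh; chromosome 11, 106300271 to 106301865) fell. Prl measured 0.73 ± 1.11 CPM with cocaine (n = 30) and 14.6 ± 16.8 CPM with saline (n = 30), a log2 change of -4.25 (SE 0.39, edgeR adjusted p = 1.94e-16), with 0 of 30 cocaine libraries above the saline median. Gh differed by -2.69 (SE 0.39, adjusted p = 1.27e-06). Banp, a nuclear DNA-binding protein gene (chromosome 8, 121949750 to 122029258), rose from 18.1 ± 2.35 to 24.2 ± 5.78 CPM (0.41, SE 0.07, adjusted p = 3.15e-04, 27 of 30), and the collagen hydroxylase gene P4ha1 rose by 0.26 (SE 0.05, adjusted p = 0.0019, 28 of 30). Narf (0.17, adjusted p = 0.0019), Rbm12b1 (0.24, adjusted p = 0.0032) and Mxd4 (0.15, adjusted p = 0.0330) also rose, and Rbm11 (-0.23, adjusted p = 0.0116) and Rfesd (-0.15, adjusted p = 0.0084) fell. These were the 5 genes that rose and the 4 that fell. Of 45 immediate early genes 0 passed, and 9 were higher adjusted over the list alone (camera adjusted p = 3.79e-09; adjusted p = 0.224 with an estimated correlation), Fos differing by 0.56 (SE 0.16, adjusted p = 0.206). Within series 1200 the differences were -0.59 (SE 1.68) for Prl, -1.34 (SE 1.2) for Gh, 0.12 (SE 0.06) for Banp and 0.03 for P4ha1. They were 0.21 (SE 0.05, adjusted p = 0.455) for Narf and 0.30 (SE 0.08, adjusted p = 0.606) for Rbm12b1. The 1 gene that passed there was Lcn2 (4.32, SE 0.48, adjusted p = 3.61e-06), an iron-binding protein of acute inflammation, named after its value was seen. Lcn2 averaged 1.075 CPM with cocaine (n = 8) and 0.050 CPM with saline (n = 17) in that series. With the series as a covariate 3 genes passed, Lcn2 among them, and 0 of the 9 genes above. Narf (0.19, SE 0.05), Rbm12b1 (0.29, SE 0.08) and Mxd4 (0.19, SE 0.06) did not shrink in that fit. The others did: Banp (0.10, SE 0.11), P4ha1 (0.03, SE 0.08), Prl (-2.10, SE 0.66), Gh (-2.43, SE 0.88), Rbm11 (-0.12, SE 0.08) and Rfesd (-0.10, SE 0.05).

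In VTA, Prl fell from 80.8 ± 146 CPM (n = 29) to 2.79 ± 6.99 CPM (n = 29), by 5.45 on the log2 scale (SE 0.58, edgeR adjusted p = 1.94e-11), and Gh (-3.49, SE 0.53, adjusted p = 9.70e-06) and Pomc, the precursor of ACTH and beta-endorphin (-2.37, SE 0.40, adjusted p = 3.26e-04), fell with it. Of 8 pituitary genes measured in VTA, 5 fell, and 6 adjusted over the list alone (median log2 change -2.81, camera adjusted p = 8.14e-07; adjusted p = 0.113 with an estimated correlation). Fam107a, a stress-responsive actin-binding protein gene, rose by 0.29 (SE 0.06, adjusted p = 0.0091, 28 of 29 libraries above the saline median), P4ha1 by 0.26 (SE 0.06, adjusted p = 0.0197), Vegfa, a vascular growth factor (chromosome 17, 46016993 to 46032369), by 0.21 (SE 0.05, adjusted p = 0.0197) and Banp by 0.36 (SE 0.08, adjusted p = 0.0317). Within series 1200 the differences were 0.55 (SE 3.14) for Prl, -0.42 for Gh, -1.12 (SE 0.73) for Pomc, 0.21 (SE 0.09) for Fam107a, 0.03 for Vegfa and 0.01 for Banp, and 1 of all genes passed, Lcn2. With the series as a covariate 9 genes passed and 0 of the 13 did. Besides Lcn2, which alone passed within series 1200, these were Gabra6 (3.60), Fat2 (3.29), Mybpc1 (2.44), Pcp2 (2.33) and Cbln3 (2.27), all higher. Crtam (2.025), Gdf10 (1.84) and Myl4 (1.33) were higher too. They were named after their values were seen, and the source of their rise in the fit with the covariate was not tested. In that fit Prl differed by -2.57 (SE 0.92), Gh by -2.33 (SE 0.99), Pomc by -1.62 (SE 0.71) and Fam107a by 0.22 (SE 0.10), each at an adjusted p of 1.0. Over all numbers 6 genes rose and 7 fell.

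**Figure D3:**
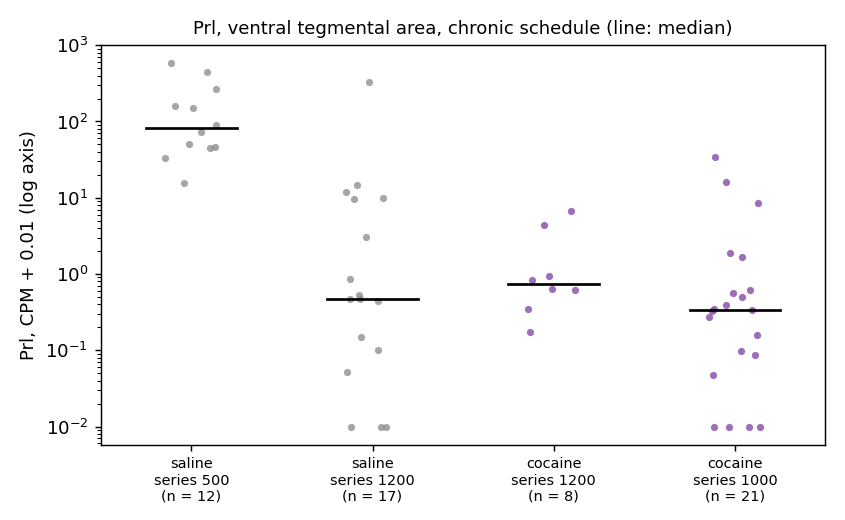
Prl in VTA on the chronic schedule, in CPM plus 0.01 on a log axis, 1 point per library with a line at the median, by treatment and number series of the sample titles. Saline libraries of series 500 (n = 12) have a median of 81.7 CPM, saline libraries of series 1200 (n = 17) 0.457 CPM, cocaine libraries of series 1200 (n = 8) 0.730 CPM and cocaine libraries of series 1000 (n = 21) 0.331 CPM.

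PFC had the most genes past the threshold with chronic cocaine, 756 higher and 593 lower. Among the largest rises were genes typical of striatal neurons: the dopamine receptor gene Drd2 (chromosome 9, 49340627 to 49408177) went from 3.54 ± 4.56 CPM (n = 26) to 8.07 ± 9.30 CPM (n = 28), by 1.18 (SE 0.31, edgeR adjusted p = 0.0130, 22 of 28), and the adenosine receptor gene Adora2a (chromosome 10, 75316877 to 75334784) went from 4.67 ± 6.01 to 11.5 ± 16.9 CPM (1.19, SE 0.34, adjusted p = 0.0226, 22 of 28). Of 25 striatal genes 17 rose, and 22 adjusted over the list alone (camera adjusted p = 6.94e-10; adjusted p = 0.558 with an estimated correlation). Of 45 immediate early genes 12 rose and 0 fell, and 19 rose adjusted over the list alone (camera adjusted p = 9.13e-05; adjusted p = 0.648 with an estimated correlation), among them Egr2 (1.01, SE 0.18, adjusted p = 8.03e-04) and Nr4a2 (0.63, SE 0.13, adjusted p = 0.0029). Of 28 glucocorticoid-induced genes 4 rose, including Fkbp5 (0.22, SE 0.05, adjusted p = 0.0103), and 13 adjusted over the list alone (camera adjusted p = 8.04e-04; adjusted p = 0.558 with an estimated correlation). Tmem232 fell by 0.85 (SE 0.16, adjusted p = 9.58e-04), with 0 of 28 cocaine libraries above the saline median, and the lymphocyte receptor gene Cd6 fell by 0.77 (SE 0.16, adjusted p = 0.0027). Within series 1200, Drd2 differed by 0.48 (SE 0.46), Adora2a by 0.42 (SE 0.48), Tmem232 by -0.58 (SE 0.27) and Cd6 by -0.68 (SE 0.28), and 1 of all genes passed, Lcn2. Drd2 differed by 0.91 (adjusted p = 0.0607) and Adora2a by 0.88 (adjusted p = 0.102) without the libraries that stand apart. With the number series as a covariate 1 gene passed, again Lcn2, and with limma voom 2661 did.

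In Nac, 13 genes rose and 10 fell with chronic cocaine. Banp rose from 15.7 ± 2.23 CPM (n = 28) to 21.8 ± 6.15 CPM (n = 29), by 0.48 (SE 0.09, edgeR adjusted p = 8.90e-04, 26 of 29). The Y-linked genes Kdm5d (1.95, SE 0.34, adjusted p = 6.07e-04), Ddx3y (1.85), Uty (1.87) and Eif2s3y (1.70) were higher, where 2 female cocaine libraries hold male transcripts. Without the libraries that contradict their labels the count was 8. The cold-inducible RNA-binding protein gene Cirbp fell by 0.33 (SE 0.08, adjusted p = 0.0408) and the meningeal sulphate transporter gene Slc13a4 by 1.77 (SE 0.41, adjusted p = 0.0395). Of 26 mural and meningeal genes 1 fell, and 17 adjusted over the list alone, with 1 higher (camera adjusted p = 1.34e-04; adjusted p = 0.706 with an estimated correlation). Within series 1200 Banp differed by 0.14, Cirbp by -0.14 and Slc13a4 by -1.74 (SE 0.82, adjusted p = 1.0). In that series 3 genes passed. They were Lcn2 (3.11, SE 0.43, adjusted p = 7.50e-04) and the immediate early genes Arc (0.82, SE 0.13, adjusted p = 0.0156) and Dusp1 (0.43, SE 0.07, adjusted p = 0.0188). Arc and Dusp1 were named after their values were seen. Lcn2 averaged 1.154 CPM with cocaine (n = 8) and 0.123 CPM with saline (n = 18) there. With the series as a covariate edgeR called 0 genes. In a fit without the libraries that stand apart, Banp differed by 0.40 (adjusted p = 0.0839). Cirbp differed by -0.25 (adjusted p = 0.324) and Slc13a4 by -0.50 (adjusted p = 0.710) in that fit. The effect of chronic cocaine differed between sex and housing combinations for 10 genes in Nac, among them Ddx3y (adjusted p = 0.0014), Eif2s3y (0.0022) and Ttr (0.0052), for 3 without the libraries that contradict their labels and for 0 without those that stand apart. DESeq2 called 26 and limma voom 1. In AMY, PFC and VTA that test gave 0 genes with edgeR, DESeq2 and limma voom, with 273, 485 and 165 at an unadjusted p under 0.05.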

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

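All tests of the explanations below were chosen after the results were seen, while the search for far-off libraries and the counts over other splits were planned, except that 12 of the 48 counts of genes belong to comparisons added after the data were examined (sex and housing over all groups, and chronic against acute cocaine).

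Pituitary hormone transcripts were lower with chronic cocaine in AMY and VTA. Repeated cocaine as the whole cause is argued against by number series 1200, the only series with both treatments, where the mean of the pituitary list over AMY and VTA differed by -0.110 (SE 0.087, range of 2 SE -0.284 to 0.065, n = 8 and 19, exact permutation p = 0.396) against -0.483 over all numbers (n = 31 and 33). Within chronic saline the list was 2.61 ± 0.286 in series 500 (SD, n = 14) and 1.51 ± 0.329 in series 1200 (n = 19), with a permutation p of 1e-05, the smallest that 100000 resamples can give. In VTA the medians of these saline libraries (n = 12 in series 500 and 17 in series 1200) were 81.1 against 0.461 CPM for Prl, 134 against 1.60 CPM for Gh and 41.6 against 1.77 CPM for Pomc, though 1 library of series 1200 reached 328 CPM of Prl. In chronic cocaine libraries of series 1000 in VTA (n = 21), the medians were 1.71 CPM for Gh and 1.76 CPM for Pomc. Single libraries among them reached 267 CPM of Gh and 132 CPM of Pomc, so high values were not confined to series 500 or to saline. A candidate explanation is pituitary tissue or RNA that entered the libraries of series 500. There 9 of 10 pituitary genes had the higher mean in VTA, and Prl was at least 1.02 CPM in each of the 45 libraries. A smaller effect of cocaine stays open.

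The genes past the threshold with chronic cocaine in PFC had a median log2 change of 0.229 in their own direction (median SE 0.065, 1349 genes). With the number series in the model the median was 0.069 (median SE 0.099) and 1 gene passed, so the series may account for much of the pattern, though these genes were chosen on the same libraries and their values would shrink in part for that reason. Between series 500 and 1200 of chronic saline, 2111 genes differed in PFC (n = 10 and 16), and 615 of them were among the 1349 against 179 for independent lists, all 615 in the opposite direction, where series 500 is itself part of the saline arm. Striatal tissue in some PFC libraries cannot be told apart as a cause: with the striatal mean in the model the median was 0.126 and 20 genes passed, while without the 7 libraries that stand apart, 2 of them by striatal genes, it was 0.201 and 420 of the 1349 passed again. Repeated cocaine cannot be told apart either: within series 1200 the median was 0.082 (quartiles 0.033 and 0.177) with 90.8% of genes in the same direction, but those libraries helped to choose the genes. Chosen between series 1000 and 500 instead, 3337 genes had a median change of 0.329 there. Within series 1200 they changed by a mean of 0.039 (SE 0.066, n = 8 and 16, exact permutation p = 0.556). The 1196 of them among the 1349 (median 0.409 where chosen) changed by 0.098 (SE 0.078, exact permutation p = 0.227), though series 1200 helped to choose the 1349.

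Lcn2, an iron-binding protein of acute inflammation, was singled out because within series 1200 it had the lowest p of all genes with chronic cocaine in each region (edgeR adjusted p = 3.61e-06 in AMY, 7.50e-04 in Nac, 2.38e-05 in PFC and 1.40e-06 in VTA), and log2 of its CPM plus 0.1, averaged over regions, was higher by 2.37 (SE 0.564, n = 8 and 19 numbers). A larger amount of blood of like makeup as the whole cause is argued against by the haemoglobin genes. They differed by 0.463 (SE 0.186, exact permutation p = 0.005), though with a larger constant added to the CPM than for Lcn2. Neutrophil genes differed by 0.128 (SE 0.137, exact permutation p = 0.279). Their mean log2 values of -2.54 with cocaine and -2.67 with saline are so low that a change could hardly show. An event in single libraries is argued against by the correlation of Lcn2 between regions of the same number, with a median Spearman rho of 0.658 over 6 pairs of regions (0.575 to 0.782, n = 22 to 25, permutation p at most 0.0066, Pearson r 0.786 to 0.904 at permutation p = 1e-04 each, the smallest that 10000 resamples can give, and 0.697 to 0.851 without the 2 farthest numbers), and with rho from 0.786 to 0.952 among the 8 cocaine numbers alone and -0.059 to 0.444 among the saline ones. Cocaine acting alike in every series is argued against by series 1000, where 1 of 24 chronic cocaine numbers reached 0.5 CPM against 6 of 8 in series 1200, on which the gene was chosen (Fisher's exact p = 2.02e-04, for this gene alone), and 0 of 19 saline numbers of series 1200, while 2 of 14, 2 of 15 and 2 of 16 saline numbers did in series 500, 1000 and 1100. An inflammatory event behind some of the samples of series 1200 may remain as an explanation, and it was not tested.

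The effect of acute cocaine differed between combinations of sex and housing for 56 genes in VTA, of which 19 are among the 25 measured choroid plexus genes, and for 4 without the libraries that stand apart. The effect of chronic cocaine differed for 10 genes in Nac, Y-linked genes among them, where 2 female cocaine libraries hold Y-linked transcripts (8.472% and 35.022% of the male median), for 3 genes without the libraries that contradict their labels and for 0 without those that stand apart.

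Single libraries lay far from the rest of their group for 6 of 64 groups in total counts and 18 of 64 in opposite-sex transcripts. In Crym this held for 6 of 16 AMY groups. Chance would flag about 1 in 20 groups if values within a group followed a normal distribution. Each flagged library was the highest of its group, and values with a long upper tail are flagged more often. The counts of flags therefore cannot be set against that rate. Total counts, in mega-counts (M), were 30.64 M in replicate 6 of AMY isolated males with chronic saline, 27.27 M in replicate 4 of Nac group-housed males with chronic cocaine, 33.69 M in replicate 7 of PFC isolated females with chronic cocaine, 52.34 M in replicate 2 of PFC isolated females with chronic saline, 36.40 M in replicate 6 of VTA group-housed females with chronic cocaine and 51.34 M in replicate 4 of VTA isolated males with chronic saline. Crym reached 76.302 CPM in replicate 2 of the group-housed females with acute cocaine, 276.826 CPM in replicate 2 of the isolated females with acute saline and 101.710 CPM in replicate 2 of those with chronic saline. It reached 95.362 CPM in replicate 2 of the group-housed males with acute cocaine, 76.560 CPM in replicate 4 of the isolated males with chronic cocaine and 114.498 CPM in replicate 1 of those with acute saline.

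Y-linked transcripts of female libraries, as a percentage of the male median, stood out at 5.870% in AMY (isolated, acute cocaine, replicate 1). In Nac they were 8.472% (group-housed, chronic cocaine, replicate 2), 0.351% (group-housed, chronic saline, replicate 1), 0.476% (isolated, acute cocaine, replicate 1) and 35.022% (isolated, chronic cocaine, replicate 6). In acute saline groups they were 0.739% in PFC (group-housed, replicate 4), 0.320% in PFC (isolated, replicate 5) and 0.632% in VTA (group-housed, replicate 4). Xist of male libraries, as a percentage of the female median, was 0.482% (group-housed, acute cocaine, replicate 3), 0.966% (group-housed, chronic saline, replicate 5) and 0.937% (isolated, chronic cocaine, replicate 2) in AMY. In isolated males of Nac it was 4.132% (acute cocaine, replicate 2), 1.275% (chronic cocaine, replicate 7) and 0.418% (acute saline, replicate 2). In PFC it was 0.936% (group-housed, acute saline, replicate 2) and 1.145% (isolated, chronic saline, replicate 7), and in isolated males of VTA 1.760% (chronic cocaine, replicate 1) and 4.475% (chronic saline, replicate 6).

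Other splits of the same libraries, 40 per comparison with the real one included, were run for 48 counts of genes. For 13 counts, 6 of them from the added comparisons, 1 of 40 splits, the real one, gave as many genes. In AMY these were sex in group-housed (15 genes, highest other 2) and isolated saline mice (13, other 1) and chronic against acute cocaine in series 1000 (2063, other 1). In PFC they were sex in isolated mice (13, other 1), sex over all groups (199, other 14), acute cocaine (11, other 0), chronic cocaine (1349, other 7) and chronic against acute cocaine (1944, other 0). In VTA they were sex in group-housed mice (11, other 4), sex over all groups (60, other 33), chronic cocaine (13, other 1) and chronic against acute cocaine (4208, other 0), and in Nac chronic against acute cocaine (730, other 0). No rank below 1 in 40 can be reached, and 48 counts were compared, so this rank alone excludes chance for none of them. On X or Y lay 15 of 15 saline sex genes in AMY (group-housed), 12 of 13 in AMY (isolated), 11 of 13 in PFC (isolated) and 11 of 11 in VTA (group-housed). Real sex labels separate such genes in any case and shuffled ones do not. Other splits gave as many genes for sex over all groups in AMY (373, other 1671, 2 splits as large), chronic cocaine in AMY (9, other 58, 2 splits) and housing in males of AMY (1, other 1, 5 splits). In Nac they did so for sex in group-housed (17, other 155, 10 splits) and isolated mice (14, other 779, 3 splits), sex over all groups (47, other 539, 2 splits), chronic cocaine (23, other 482, 3 splits) and its differences between combinations (10, other 636, 21 splits). The same holds for sex in group-housed mice in PFC (11, other 304, 2 splits), sex in isolated mice in VTA (12, other 895, 3 splits) and the 56 genes of VTA (other 273, 11 splits). For the 24 counts of 0 this comparison decides nothing, since every split gives at least 0, and another split reached up to 1524 genes. The splits were drawn without regard to the number series, which nearly coincides with chronic cocaine. The counts of chronic cocaine are thus not set apart from the series, and with the series as a covariate chronic cocaine gave 1 gene in PFC, 3 in AMY, 0 in Nac and 9 in VTA, of which 1 in PFC and 0 elsewhere had passed without it. Splits that call many times the real count point to a structure of the samples other than the groups.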

How the results depend on the processing

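Fits without libraries that stand apart, of single schedules and of single number series were chosen after the data were examined. Of 414 counts under another setting, 328 stayed within 1.5 times the reported one and 86 did not, and 14 values of named genes turned direction under a setting. The cause was not tested, though single schedules and series and fits without some libraries hold fewer samples. No paired analysis was possible because within a region every library has its own number. With size factors by RLE, 0 of 239 calls of named genes were lost. Lost were 37 of 239 with limma voom and as many without a filter on low counts, 1 of 230 with DESeq2, 39 of 149 with the number series as a covariate and 27 of 149 with 3 surrogate variables. Without the libraries that stand apart 50 of 238 were lost, and 14 of 126 without those that contradict their labels. In series 1000, 1100 and 1200 alone 5 of 9, 7 of 9 and 36 of 38 were lost, and in acute and chronic saline groups alone 2 of 2 and 1 of 2. Leaving out any of the 5 isolated males with acute cocaine in AMY changed no direction among 8 gene values, none of which had passed before. With 3 surrogate variables the counts were 26 for sex in group-housed mice, 88 for chronic cocaine, 8 for acute cocaine differing between combinations and 922 for sex over all groups in AMY, 23 (sex in isolation), 1 (acute differing), 5 (chronic differing) and 127 (sex over all groups) in Nac, 49 (chronic cocaine), 1 (chronic differing) and 468 (sex over all groups) in PFC, and 20 (sex in isolation), 48 (acute), 44 (chronic), 1 (acute differing) and 177 (sex over all groups) in VTA. With limma voom they were 20 (sex in isolation), 0 (housing in males), 576 (sex over all groups) and 3889 (chronic against acute) in AMY, 23 (sex in isolation), 92 (chronic), 9 (acute differing), 1 (chronic differing), 185 (sex over all groups) and 4041 (chronic against acute) in Nac, 20 (sex in isolation), 143 (acute), 2661 (chronic), 16 (acute differing), 313 (sex over all groups) and 4200 (chronic against acute) in PFC, and 404 (acute), 34 (chronic), 2391 (acute differing) and 100 (sex over all groups) in VTA. With DESeq2 they were 0 (housing in males), 19 (chronic) and 4 (acute differing) in AMY, 38 (sex in isolation), 2 (acute), 104 (chronic), 1 (acute differing), 26 (chronic differing) and 1257 (chronic against acute) in Nac, and 13 (acute) and 93 (acute differing) in VTA. With the number series as a covariate, chronic cocaine gave 3 genes in AMY, 0 in Nac and 1 in PFC, and acute cocaine 3 in VTA. Without a filter on low counts they were 1 (housing in males), 13 (chronic) and 326 (chronic against acute) in Nac and 745 (chronic), 103 (sex over all groups) and 1283 (chronic against acute) in PFC. Without the libraries that contradict their labels, Nac gave 8 (chronic), 3 (chronic differing) and 1991 (chronic against acute). Without the libraries that stand apart, AMY gave 0 (housing in males), Nac 1 (chronic), 0 (chronic differing) and 2587 (chronic against acute), PFC 32 (acute), 428 (chronic), 123 (sex over all groups) and 882 (chronic against acute), and VTA 4 (acute differing). Acute saline groups alone gave 28 (sex in group housing) and 1 (housing in males) in Nac and 20 (sex in group housing) and 6 (housing in females) in PFC. Chronic saline groups alone gave 1 (sex by housing) and 0 (housing in males) in AMY and 32 and about 1.2e+03 (sex in group housing and isolation), 171 (sex by housing), 15 (housing in males) and about 1.1e+03 (housing in females) in Nac. Series 1000 alone gave 496 genes with acute cocaine in VTA, series 1100 alone 2 in PFC, and series 1200 alone 1, 3, 1 and 1 with chronic cocaine in AMY, Nac, PFC and VTA. Crym of AMY turned direction for sex in group housing with limma voom (0.152) and without libraries that stand apart (0.050), for acute cocaine with the series covariate (0.010), limma voom (0.064) and series 1100 only (0.350), and for chronic cocaine with the series covariate (-0.022), 3 surrogate variables (-0.076) and series 1200 only (-0.159). With chronic cocaine in PFC, Igfbpl1 (-0.100) and Clic6 (-0.021) turned with 3 surrogate variables and Slc26a7 with the series covariate (0.303) and series 1200 only (0.172). Slc17a8 of VTA with acute cocaine was 0.346 in series 1000, and Prl of VTA with chronic cocaine 0.550 in series 1200.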

Other observations

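The comparison of chronic with acute cocaine within number series 1000 and the tests of Crym and of sex under isolation were chosen after the data were examined.

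Within series 1000, genes known to be induced by glucocorticoids were lower on the chronic than on the acute cocaine schedule in each region. Of 28 such genes, 15 were lower in AMY, 16 in Nac, 18 in PFC and 21 in VTA (adjusted p = 0.0142, 0.0013, 6.26e-04 and 0.0071 with an estimated correlation). Sgk1, a kinase gene induced by glucocorticoids, fell by 2.07 on the log2 scale in VTA (SE 0.11, edgeR adjusted p = 3.94e-14), from 212 ± 38.7 CPM (SD, n = 16) to 50.26 ± 15.04 CPM (n = 21), with all 21 chronic libraries below the acute median. It fell by 1.02 in AMY (SE 0.10, adjusted p = 4.15e-08, 22 of 22 libraries), 0.77 in Nac (SE 0.07, adjusted p = 1.25e-08, 21 of 21) and 0.65 in PFC (SE 0.06, adjusted p = 1.03e-09, 20 of 20). Arc, a synaptic gene that neuronal activity switches on, fell in PFC from 179 ± 45.4 CPM (n = 15) to 59.9 ± 28.8 CPM (n = 20), by 1.60 (SE 0.16, adjusted p = 4.25e-08, 20 of 20). In PFC 37 of 45 immediate early genes were lower and 1 higher (adjusted p = 6.39e-05 with an estimated correlation), and in VTA 23 of 44 were lower and 1 higher (adjusted p = 0.0071). In AMY 23 of 45 were lower and 2 higher, and in Nac 13 of 45 were lower (adjusted p = 0.171 and 0.293 with an estimated correlation).

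In all, 1116 genes were higher and 947 lower on the chronic schedule in AMY (n = 22 and 14), 447 and 283 in Nac (n = 21 and 14), 1944 in PFC, 910 of them lower (n = 20 and 15), and 2020 and 2188 in VTA (n = 21 and 16). The count moved with the setting: the 730 genes of Nac became 2587 without the libraries that stand apart, 1991 without those that contradict their labels, 326 without a filter on low counts, 1257 with DESeq2 and 4041 with limma voom. The 1944 of PFC became 882 without the libraries that stand apart, 1283 without the filter and 4200 with limma voom, which gave 3889 in AMY against 2063. Among the largest changes in VTA, the peptide gene Cartpt was at 2.88 CPM on the chronic and 67.6 CPM on the acute schedule (edgeR adjusted p = 3.13e-06, lower in 21 of 21 chronic libraries than the acute median), and Rln3, a peptide gene of the brainstem, was at 19.96 against 1.73 CPM (adjusted p = 1.67e-07, higher in 20 of 21). In AMY the acetylcholine synthesis gene Chat was higher by 3.00 (SE 0.81, adjusted p = 0.0158, 16 of 22 libraries) and Greb1 fell by 1.90 (SE 0.36, adjusted p = 0.0015, 18 of 22). The title numbers of the schedules do not interleave within the series, so schedule and order of the numbers cannot be separated. The series also holds no chronic saline, so a change that needs cocaine cannot be told from one that comes with the schedule alone.

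Crym varied from 7.72 to 276.8 CPM over the 115 AMY libraries, with a median of 25.4 CPM. Its log2 CPM followed the first principal component of 3000 variable genes, which holds 15.4% of their variance (Pearson r = 0.911, Spearman rho = 0.819, permutation p = 1e-04 for each, the smallest that 10000 resamples can give). Without the 2 libraries farthest from the median r was 0.894, within groups 0.910, and within series 500, 1000, 1100 and 1200 it was 0.814, 0.925, 0.910 and 0.797 (n = 13, 50, 27 and 25). Crym may mark how far a dissection reached into a neighbouring tissue or cell group. This hypothesis was not tested, and the correlation does not separate it from variation between mice.

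The hypothesis that isolation lowers the number of genes that differ by sex in AMY was tested on saline mice. At an unadjusted p under 0.05 there were 898 genes in group-housed and 1142 in isolated mice, where chance gives 870 in each. The difference, group-housed minus isolated, was -244, in the opposite direction. In 22 of 40 splits of the housing labels, the real one included, it was -244 or higher. Other splits lay between -1533 and 1809. With counts this near chance and splits this wide, the test cannot decide the hypothesis.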
